A study of Bombyx mori with 3 samples.

How the data were processed

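Total RNA from 4 developmental stages of the silkworm Bombyx mori, the moth reared for silk, was labelled with fluorescent dyes and hybridised to Agilent 2-colour arrays of 60-base probes. The insects were kept at 25 degrees and fed mulberry leaves, per the labels. The labels do not say which day of a stage, which tissue or sex, or how many insects gave each RNA, nor whether the larval or pupal RNA on 2 arrays was the same extract. There were 3 arrays, each setting a stage against the next: egg (Cy5) against larva (Cy3), larva (Cy5) against pupa (Cy3), and pupa (Cy5) against adult (Cy3). No dyes were swapped within a comparison, so a bias of a dye for a probe was not separated from the stage. All 3 arrays lay on 1 slide and came from 1 scan, per the file headers.

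The deposited scanner files hold, for each spot, the mean intensity and the median local background intensity in both channels, written by Agilent Feature Extraction 10.5.1.1, per the file headers. The same files hold the software's processed intensity, from which a spatial trend was subtracted as background and to which a linear and LOWESS dye normalization was applied, per the file headers. They also hold the log10 ratio of Cy5 over Cy3 with its error, and a p-value of that ratio from the software's error model for 1 spot, per the file headers. That p-value describes a spot and is no test between stages. Other columns are flags per spot of well above background, saturated or outlying, per the file headers. The value table deposited with the series is on the log10 scale as Cy5 over Cy3 and repeats the scanner files' ratio. Its values lay within 0.005 of that ratio at every probe spot, it was not centred again, and its column medians were 0.041, 0.00 and 0.00.

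From these files the mean intensities were corrected for local background with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 under R 4.3.3. The 536 control spots were given no weight in loess and were then left out, as were 17, 13 and 3 spots flagged as outliers on the first, the second and the third array. No probe spot was saturated. The array carries 14962 probe spots with 14647 distinct probe sequences: 14589 on 1 spot, 36 on 2, 11 on 3, 3 on 4 and 8 on 32 spots. Spots with the same sequence were averaged, and a sequence counted as measured on an array when over 0.5 of its spots were well above background in both channels. All ratios were turned to later over earlier stage and given as log2. Tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

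There was 1 array per comparison and no replicate, so no test between stages was made and no error between insects could be given. Sequences at least 2-fold apart were counted by size alone. A sequence well above background in only 1 channel has a bound in place of a ratio: its brighter signal against the higher of its own dim signal and the lowest well-measured signal of the dim channel, after loess and Aquantile, which stays open to dye bias. Technical error came from sequences on several spots and from the stages hybridised on 2 arrays. The number of arrays limits the precision.

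The probes carry only the array maker's identifiers. None of them matched an identifier among the 18210 genes of the RefSeq gene table, the files gave 1 description for all of them and no mapped position, so genes are not named here. The 35 gene lists fixed before the data were examined therefore had no members and gave no result. In their place, after the files had been seen, probe sequences were translated in the 3 forward frames and searched for 49 signatures of protein families or composition. Of the 14647 sequences, 4206 (28.7%) ended with a stop codon that closed an open forward frame, against 293 (2.0%) of their reverse complements, so the probes read in the sense direction and many end at the stop. A signature was used when at least 3 sequences held it, when hits in the reverse complements were under 0.5 of the forward hits, and, for all but composition, when hits in shuffled peptides were at most 0.25 of them. The 12 signatures used were those of serine proteases, C2H2 zinc fingers, homeodomains, protein kinases, EF-hands, cytochromes P450, WD repeats, insulins, ER retention, and glycine-rich, acidic and basic stretches. A match of so short a stretch to a signature is not an identified gene.

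Each class median was set against 10000 random lists of the same size, matched on mean signal in 10 bins, as a description of these arrays and not as a test of stages. Of 29 such medians, from classes with at least 3 measured sequences, 10 lay outside the central 95% of random lists, where chance would give 1.5 if sequences were independent. The medians are not separate trials, as a class recurs at steps that share a stage and some classes hold near-identical probes. The 10 are therefore not to be weighed against 1.5 as a test. The zinc finger class had fewer than 3 measured sequences at every step under the filter on dim probes. The rule for probes named in the text, fixed before the data were examined, was the largest ratios each way among well-measured, unsaturated probes. It was limited to 2 each way per comparison because the probes have no gene names.

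The normalization was tested on simulated data. With 14962 probes run for each of the 3 comparisons, 100% of spots with a true log2 change of 2 or -2 came out at least 2-fold apart. Of those at 1.5 this share was 91.3%, 86.4% and 82.1% at the 3 steps in order, and of those at -1.5 it was 90.5%, 88.5% and 89.3%. It was 0% of unchanged spots, and 0% of those at 0.585 or -0.585 except 3.2% of those at 0.585 for pupa against adult. The simulation changed only a small share of spots, evenly up and down, and each rate for changed spots rests on 21 to 31 spots. On the arrays themselves 33.2% to 42.4% of measured sequences were at least 2-fold apart. The rates therefore do not cover changes that are many or lie mostly on one side. The simulated noise was also smaller than the spread between 2 readings of the same stage, with SDs of 0.339 for larva and 0.306 for pupa. There 1.5% and 1.15% of sequences lay 2-fold or more apart. The 0% for unchanged spots therefore does not cover error between arrays and dyes. The class percentiles were tested the same way on 200 lists per size. A shift of 2 on the log2 scale put 84.0% of lists of 8 and 25.0% of lists of 3 outside the central range for egg against larva (11487 sequences). These were 98.5% and 52.0% for larva against pupa (11945), and 98.0% and 75.5% for pupa against adult (12380). Between 3.0% and 8.5% of unshifted lists fell there, so a small class inside the range is not shown to be unchanged.

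The alternatives tried were the scanner software's ratio, the deposited value table, median centring, no normalization, no background subtraction, an offset of 0, other filters on dim, outlying or saturated spots, a spot p-value below 0.01, and other fold thresholds for profiles. Their effects are given in the closing section. Relative to loess, whose median log ratio is near 0, the scanner software's ratio had medians of -0.448, -0.012 and 0.088 on the log2 scale at the 3 steps. Median centring, taken over all spots, left -0.239, 0.046 and -0.143 over the measured sequences, and no normalization left -0.692, -0.091 and -1.055.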

Results

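Transcript levels were compared between successive stages of silkworm development, from egg through larva and pupa to adult, to follow how expression changes over the life cycle. There were 3 arrays and 4 stages, with 1 array for each comparison and no replicate, so the differences between stages carry no error between insects and were not tested. Detection was high throughout. Of 14647 probe sequences, 11740 (80.2%) were well above background in egg and 12738 (87.0%) in larva on the first array, 12159 (83.0%) in larva and 12710 (86.8%) in pupa on the second, and 12795 (87.4%) in pupa and 12755 (87.1%) in adult on the third. The median spot stood 13.8 times above the median local background in egg, 26.6 and 14.2 times in larva (Cy3 and Cy5), 36.8 and 19.1 times in pupa, and 21.7 times in adult.

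Technical error was small beside the differences between stages, whose log2 ratios had an SD across sequences of 1.95, 1.81 and 1.64 at the 3 steps. The 32 spots of a repeated probe sequence had a pooled SD on the log2 scale of 0.088, 0.084 and 0.078 on the 3 arrays. Larval signals read in Cy3 on the first array and in Cy5 on the second correlated across 10856 probe sequences with Pearson's r = 0.993, and the 2 pupal readings with r = 0.994. Probe sequences are not independent replicates. The SD of the difference was 0.339 for larva and 0.306 for pupa on the log2 scale, and 163 (1.5%) and 125 (1.15%) of the sequences lay 2-fold or more apart after centring. Different stages correlated less: r was 0.737 for egg and larva on their shared array, 0.813 for larva and pupa, 0.841 for pupa and adult, and 0.657 for egg and adult, which were on different arrays.

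The first comparison asked how the larva differs from the egg. The very large differences lay mostly on the side of the larva: 1124 probe sequences were at least 10-fold higher in larva and 89 in egg, and 124 against 6 were at least 100-fold higher. Probes whose translations carry the active site of trypsin-family serine proteases, the calcium-binding EF-hand loop, the haem site of cytochromes P450 or the insulin family signature were higher in larva as groups. Those with the homeodomain signature of developmental transcription factors were higher in egg as a group.

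All 3 sequences with the serine protease site had higher values in larva, with log2 ratios of 6.70, 4.90 and 0.48, and the class median of 4.90 exceeded that of 99.4% of random lists. The 6 EF-hand sequences had a median of 3.12 (percentile 99.8), and 4 of them were over 2-fold higher in larva. The largest belonged to a pair of probes reading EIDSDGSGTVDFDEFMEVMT and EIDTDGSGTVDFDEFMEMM, at 5.69 and 5.57, which share much of their sequence. Among 5 measured P450 sequences, 4 were over 2-fold higher in larva and none in egg (median 2.28, percentile 97.7). Under the scanner software's ratio 3 were higher in larva and 1 in egg, and the median of 1.76 fell inside the central 95% of random lists. Of 7 measured sequences with the insulin signature, the A-chain pattern of insulin-like peptides, 5 were over 2-fold higher in larva and 1 was higher in egg, at -2.36. Their median was 1.85 (percentile 98.0). Among 4 measured homeodomain sequences, 3 were higher in egg, at -1.74, -1.76 and -2.19, while 1, reading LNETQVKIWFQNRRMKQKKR, was higher in larva at 1.90. The class median of -1.75 stood at percentile 0.25, with a mean of -0.95 and a median of -2.57 by the scanner software's ratio. These class directions held under all 4 treatments of the log ratios compared here, the loess one included. The classes of WD repeats (median -0.63), ER retention signals (1.32), and glycine-rich (0.19), acidic (-0.16) and basic (-0.02) stretches lay inside the range of random lists. With no filter on dim probes the 10 glycine-rich sequences had a median of 1.63 (percentile 98.6), outside it.

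The highest ratios in larva were those of probe sw11645, 679-fold (log2 ratio 9.41, scanner software error 0.97), and sw00716, 592-fold (9.21, error 0.89). The egg signal of sw11645 was dim, at 6.88 on the log2 scale. Its ratio was 9.73 by the scanner software and 9.87 with an offset of 0. The sequence of sw11645, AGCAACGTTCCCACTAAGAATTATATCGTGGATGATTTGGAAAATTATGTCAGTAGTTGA, reads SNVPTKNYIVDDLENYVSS before a stop. That of sw00716, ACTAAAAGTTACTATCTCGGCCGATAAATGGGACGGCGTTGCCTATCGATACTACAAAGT, has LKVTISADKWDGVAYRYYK as its open frame. Both were lower again in pupa, at -5.21 and -3.07. The highest ratios in egg were 652-fold for sw13913 (-9.35, error 1.17; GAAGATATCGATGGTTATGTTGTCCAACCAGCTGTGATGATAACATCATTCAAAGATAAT) and 432-fold for sw09144 (-8.75, error 0.97; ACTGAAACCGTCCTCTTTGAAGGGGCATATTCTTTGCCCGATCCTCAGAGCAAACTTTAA). By the scanner software's ratio sw13913 was at -11.69 and sw09144 at -9.70. Neither was well above background in larva on the second array. The latter was not so in pupa either, and was again well above background in adult.

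By the threshold of 2-fold, 2967 of 11487 measured sequences were higher in larva and 1899 in egg, so 61.0% of those apart were higher in larva. This balance turned with the scaling: 40.1% were higher in larva by the scanner software's ratio (2550 against 3808), 47.0% after median centring (2489 against 2812) and 31.2% without normalization (2020 against 4448). The excess at 10-fold kept its direction under each of these, at 1067 against 245, 964 against 130, and 797 against 217. In addition, 1235 sequences were well above background in larva but not in egg, of which 133 were at least 10-fold higher in larva by their bound. The reverse held for 236, of which 12 were at least 10-fold higher in egg. Detection of a single stage also differed between 2 arrays and dyes: in larva 700 sequences were well above background only in Cy3 and 121 only in Cy5, and in pupa 117 and 202.

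**Figure D1:**
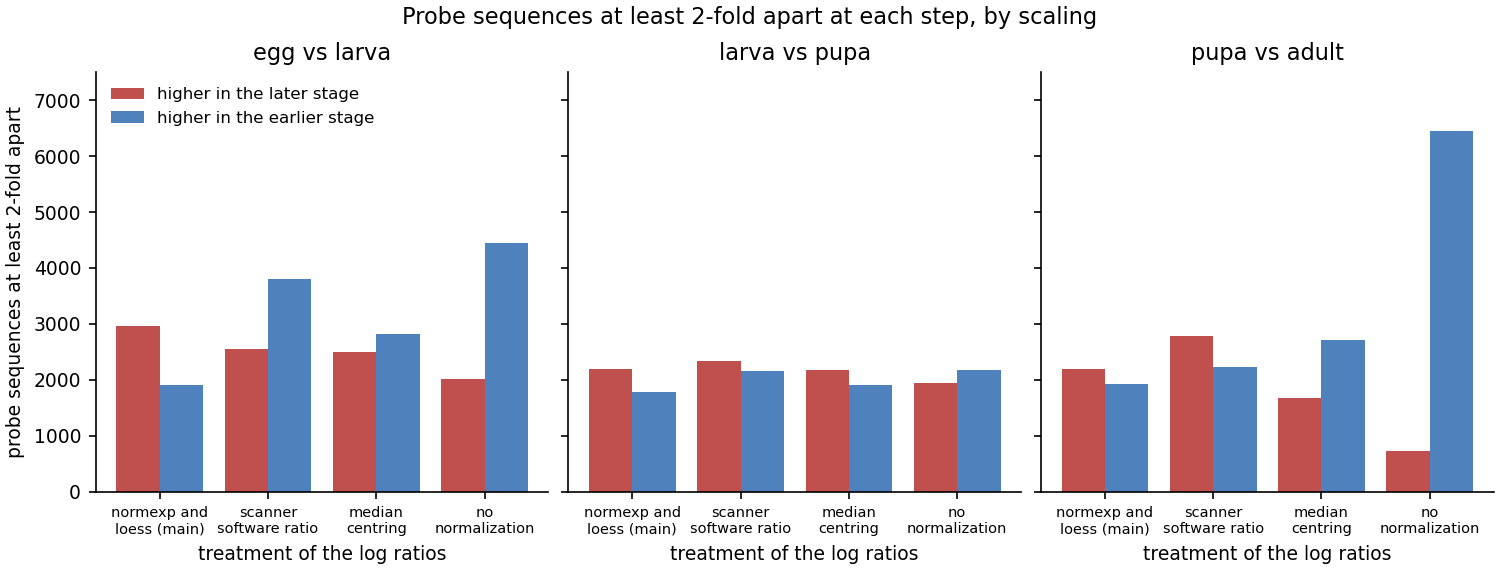
Bars give the number of probe sequences at least 2-fold higher in the later (red) or earlier (blue) stage on each of the 3 arrays, under 4 treatments of the log ratios, with 1 array per comparison and no error. For egg and larva the balance turned from 2967 against 1899 under loess to 2550 against 3808 under the scanner software's ratio, and for pupa and adult from 2185 against 1927 to 1670 against 2709 under median centring.

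The second comparison asked what changes from larva to pupa. All 8 sequences with the insulin signature were lower in pupa, within a narrow range of -2.52 to -1.41. The serine protease and P450 classes, which had been higher in larva than in egg, were lower in pupa as groups. The insulin class median of -1.97 stood at percentile 0.01 of random lists, and 8 of 8 members stayed over 2-fold lower under the scanner software's ratio (median -2.50), median centring (-1.85) and no normalization (-1.99). Under loess the largest drop was that of the probe reading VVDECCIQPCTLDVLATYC before a stop, at -2.52, while by the scanner software's ratio that of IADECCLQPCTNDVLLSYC was larger (-3.32 against -3.09). The smallest drop under loess was that of the probe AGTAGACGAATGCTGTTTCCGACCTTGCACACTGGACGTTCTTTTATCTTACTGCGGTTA, which reads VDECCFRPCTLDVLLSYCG. Of the 3 serine protease sequences, 2 were far lower in pupa, at -7.86 and -5.70, and the other was higher, at 1.5 (median -5.70, percentile 0.07). All 5 measured P450 sequences had negative ratios, 3 of them over 2-fold (median -1.29, percentile 2.08). The EF-hand sequences split: 2 were lower in pupa, at -4.54 and -4.45, and 1 was higher, at 4.75 (median 0.34, percentile 77.3). The 2 that share the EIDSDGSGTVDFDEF and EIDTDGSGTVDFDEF stretches went opposite ways. The kinase (-0.08), WD repeat (0.33), ER retention (-0.54), glycine-rich (-0.25), acidic (0.21) and basic (0.04) classes lay inside the range of random lists. The zinc finger class had 3 sequences only with no filter on dim probes, and their median of -0.37 (percentile 1.1) lay outside it.

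The largest differences were on the larval side. Probe sw10175, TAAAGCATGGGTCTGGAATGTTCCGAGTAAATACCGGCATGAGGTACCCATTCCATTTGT, was 3949-fold higher in larva than in pupa (log2 ratio -11.95, error 1.31), after a ratio of 8.04 from egg to larva. Probe sw09901, with the open frame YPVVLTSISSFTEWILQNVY from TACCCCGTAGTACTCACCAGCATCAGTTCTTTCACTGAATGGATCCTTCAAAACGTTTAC, was 1406-fold higher in larva (-10.46, error 1.1). The pupal signal of sw10175 was dim, at 6.86 on the log2 scale. Its ratio was -13.09 by the scanner software and -12.78 with an offset of 0, so the fold is approximate. Higher in pupa were sw01817, 375-fold (8.55, error 0.88), and sw14376, 169-fold (7.40, error 0.74). The sequence of sw01817, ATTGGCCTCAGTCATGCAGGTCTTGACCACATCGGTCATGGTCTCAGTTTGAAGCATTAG, reads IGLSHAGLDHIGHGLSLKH before a stop, and its ratio from pupa to adult was -9.41. Counts at 10-fold were near even, with 544 sequences higher in pupa and 470 in larva, but at 100-fold 128 were higher in larva and 8 in pupa.

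At 2-fold, 2187 of 11945 measured sequences were higher in pupa and 1781 in larva, so 55.1% were higher in pupa, against 51.9% by the scanner software's ratio and 47.3% without normalization. Another 752 sequences were well above background in pupa but not in larva, and 201 in larva but not in pupa. By their bounds, 41 of the former and 26 of the latter were at least 10-fold apart.

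The third comparison asked what changes from pupa to adult. The insulin signature sequences had ratios nearer 0 at this step, with a median of 0.18 (percentile 77.7) and values from -0.19 to 1.35, though without normalization their median was -0.67. By the scanner software's ratio their values ran from -0.20 to 2.53 (median 0.40), with 2 over 2-fold higher in adult. The P450 class had a median of 0.83 (percentile 98.1), with 3 of 6 sequences over 2-fold higher in adult and 1 in pupa, but its median was -0.09 without normalization. With no filter on dim probes the median of 7 was 0.48 (percentile 94.3), inside the central 95% of random lists. The pair of P450 probes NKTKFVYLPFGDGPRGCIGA and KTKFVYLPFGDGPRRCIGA, which are near-identical, had ratios of 2.31 and 2.25. The basic class, 87 sequences with an open forward frame rich in lysine and arginine, was slightly lower in adult (median -0.27, percentile 0.51). In this class 17 sequences were over 2-fold higher in pupa and 9 in adult. The frame need not be the translated one, and an effect of base composition was not tested for this class. The size of this class difference depended on the scaling: the median was -0.48 after median centring (32 against 8) and -1.4 without normalization (59 against 2). These scalings differ only by a constant for the whole array, so class percentiles were the same under both. They were 98.89 for P450, 73.73 for insulin and 2.24 for basic. The kinase (1.29), EF-hand (-0.10), WD repeat (-0.57), ER retention (-0.18), glycine-rich (0.70) and acidic (-0.09) classes lay inside the range of random lists. The serine protease probe that had been higher in pupa than in larva, reading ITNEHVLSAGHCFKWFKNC before a stop, was higher still in adult, at 5.52, while the other measured member of its class was lower in adult, at -1.05.

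**Figure D2:**
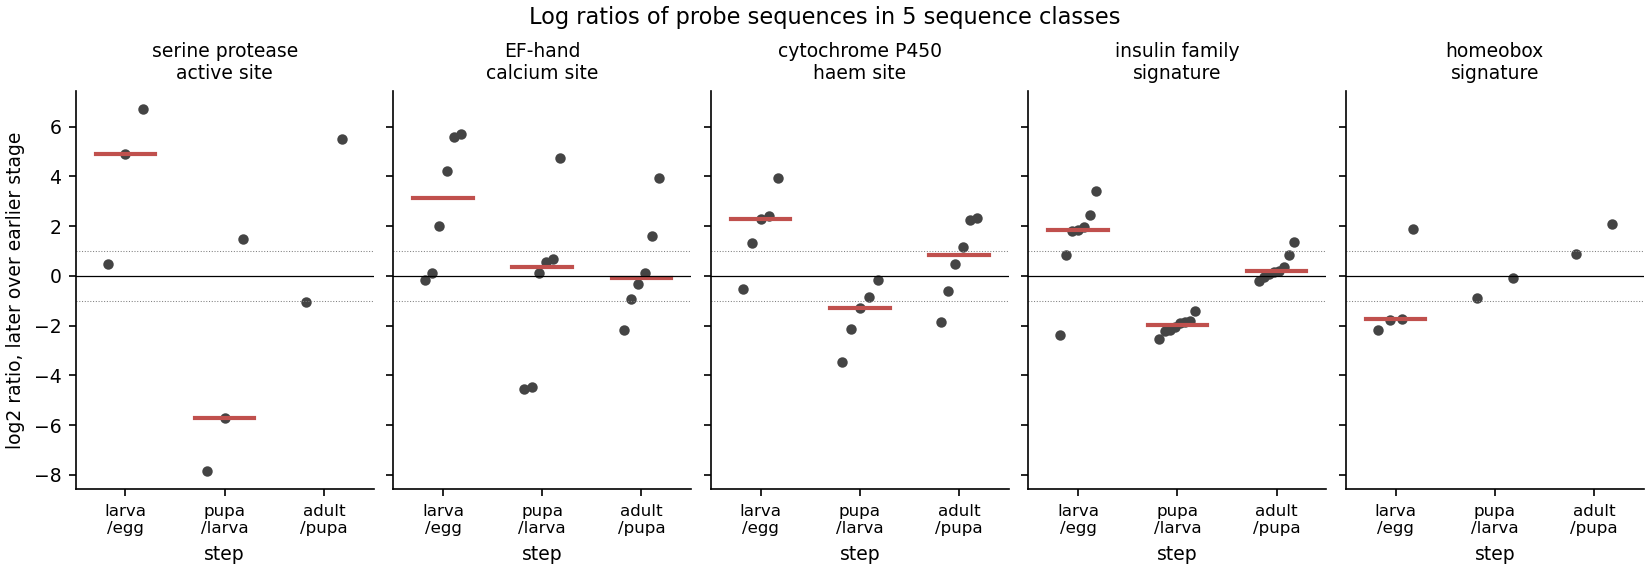
Each point is the log2 ratio of a probe sequence between successive stages (later over earlier), for 5 classes of translated signature. Red lines are medians of at least 3 measured sequences, dotted lines mark 2-fold, and there is 1 array per step. The 8 insulin signature sequences lie between -2.52 and -1.41 from larva to pupa, while the EF-hand sequences spread from -4.54 to 4.75 at that step.

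Probe sw08284 was 229-fold higher in adult than in pupa (log2 ratio 7.84, error 0.78), after ratios of 0.26 and 3.15 at the earlier steps. Its sequence, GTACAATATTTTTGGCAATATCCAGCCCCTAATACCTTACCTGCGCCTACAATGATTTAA, reads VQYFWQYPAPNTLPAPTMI before a stop. Probe sw14356, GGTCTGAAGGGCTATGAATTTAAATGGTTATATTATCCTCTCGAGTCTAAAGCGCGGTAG, was 181-fold higher in adult (7.50, error 0.77). Lower in adult were sw14376 by 1177-fold (-10.20, error 1.13) and sw03082 by 760-fold (-9.57, error 1.02). The former, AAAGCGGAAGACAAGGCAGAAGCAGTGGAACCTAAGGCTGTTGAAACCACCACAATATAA, was also among the largest increases from larva to pupa, so its signal was highest in pupa. The latter, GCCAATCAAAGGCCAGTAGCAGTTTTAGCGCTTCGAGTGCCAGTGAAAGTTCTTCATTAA, had been higher at both earlier steps, at 7.63 and 3.12.

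At 2-fold, 2185 of 12380 measured sequences were higher in adult and 1927 in pupa, or 53.1% higher in adult. After median centring 38.1% were higher in adult (1670 against 2709), and without normalization 10.2% (729 against 6441). At 10-fold, 351 were higher in adult and 426 in pupa, against 269 and 499 after median centring and 176 and 797 without normalization. Another 372 sequences were well above background in adult but not in pupa, and 412 in pupa but not in adult.

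Across the 10856 sequences measured on all 3 arrays, 4168 (38.4%) stayed under 2-fold at every step, against 2677 (24.7%) by the scanner software's ratio. A peak in larva, higher than in egg and in pupa, was shown by 1243 sequences, against 419.1 if the steps were independent. A peak in pupa was shown by 644 (266.1 if independent), a trough in larva by 427 (273.1) and a trough in pupa by 586 (269.3). By the scanner software's ratio the trough in larva was shown by 718, against 581.4 if independent. Under loess 59 sequences were higher at every step and 4 lower, but after median centring 28 were higher and 76 lower. Adjacent steps share a stage, and independent chance values of the 4 stages give a correlation of -0.50 between the first and second step and -0.49 between the second and the third. The observed correlations across sequences were no stronger, at -0.453 and -0.233, with covariances of -1.448 and -0.587. The excess of peaks and troughs over independent steps may therefore come wholly or in part from the shared stage. The simulation reused a value per stage, whereas larva and pupa were read anew on each array, with SDs of the difference of 0.339 and 0.306. True levels that vary freely between stages would give the same correlation as chance values. The comparison therefore cannot tell chance from true peaks and troughs. Summed over the steps, 3204 sequences were at least 2-fold higher in adult than in egg and 2367 the reverse. This balance turned with the scaling, to 2772 against 3816 by the scanner software's ratio, 2307 against 3692 after median centring and 1056 against 7679 without normalization. Of all 14647 sequences, 10883 (74.3%) were well above background in every stage and on every array, 1115 (7.6%) in none, 736 (5.0%) in all but egg, 141 in adult only, 85 in egg only, 53 in pupa only and 51 in larva only. A sequence had to pass on both arrays to count as seen in larva or pupa, but on a single array for egg or adult. The counts for single stages are therefore not on equal terms.

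The 8 sequences placed on 32 spots gave the most precise ratios. Of those named here by a translation, all but the probe reading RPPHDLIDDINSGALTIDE have another open forward frame. Which frame is translated is not known, so the peptide given serves as a label. The probe reading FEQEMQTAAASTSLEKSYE was well above background on 32 of 32 spots in larva and 1 of 32 in egg. It was then higher in pupa than in larva by 3.59 ± 0.05 (SD, n = 32 spots) and lower in adult by -2.01 ± 0.02. The probe reading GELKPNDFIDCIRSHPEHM before a stop changed by 1.02 ± 0.034, -1.52 ± 0.033 and 3.87 ± 0.053 over the 3 steps. The other 6 were lower in adult than in pupa, between -1.30 and -0.61, and the probe reading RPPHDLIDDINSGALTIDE before a stop changed least at that step. After median centring these 6 lay lower, between -2.48 and -1.81. These SDs are between spots of 1 array and leave out any difference between insects. The scaling moved several of these ratios by more. From larva to pupa the probe with the open frames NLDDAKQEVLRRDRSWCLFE and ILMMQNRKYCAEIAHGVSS turned from 0.21 under loess to -1.27 after median centring. It was at 0.41 by the scanner software's ratio. The first step of the probe reading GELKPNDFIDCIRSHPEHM was 0.55 by the scanner software's ratio and 0.61 after median centring, under 2-fold, and the probe reading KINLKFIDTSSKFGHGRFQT had -1.12 from larva to pupa under loess, -0.88 by the scanner software's ratio and -2.70 after median centring.

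**Figure D3:**
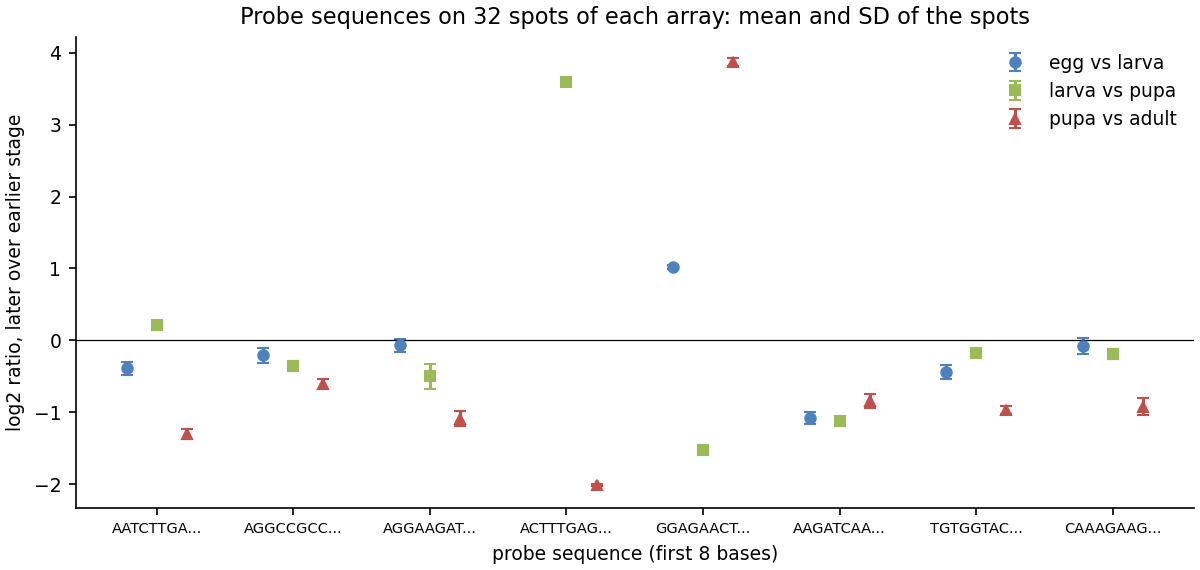
Mean log2 ratio (later over earlier stage) and SD of the 32 spots of each of 8 probe sequences on the 3 arrays, named by their first 8 bases. Error bars cover spots of 1 array only. The first step is not drawn for the sequence that was well above background in egg on 1 of 32 spots. Under loess the ratios drawn run from -2.01 to 3.87.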

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

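The tests of detection and of cross-hybridisation were chosen after the results they bear on had been seen. Signals appeared in control probes that no comparison used, at 2 or more times the highest of 77 negative control spots. Control probe eQC-39 (6 spots) had a median signal above local background of 245 in egg, 1073 and 1693 in larva, 1092 and 1156 in pupa, and 86.8 in adult, the last of which did not pass that limit. Control probe eQC-41 passed it only in pupa, at 162.5 (Cy3) and 238.8 (Cy5), with 50.7 and 53.0 in larva, 38.8 in egg and 34.0 in adult. The negative control median was between 17.0 and 19.4 in these channels. No explanation of these signals was tested.

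More sequences were well above background in larva but not egg than the reverse (1235 against 236). With both stages read in Cy5, on different arrays, the counts were 1034 and 615, a ratio of 1.68. The same stage on 2 arrays gave 5.79 for larva, with more in Cy3, and 1.73 for pupa, with more in Cy5, but those pairs differ in dye as well as array, and no stage was read in Cy5 on 2 arrays. Of the 1235, 292 (23.6%, exact 95% binomial interval 21.3 to 26.1) were not well above background when larva was read in Cy5. A lower sensitivity of the egg channel may account for this excess, wholly or in part, and cannot be told apart from the stages, because egg was read once, though the pupal counts (117 only in Cy3, 202 only in Cy5) go against a lower sensitivity of Cy5 on every array.

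The excess of sequences at least 10-fold higher in larva (1124 against 89) had 3 technical explanations tested. The centring of the log ratios was argued against as the whole cause, since the ratio of the 2 counts was at least 3.67 under the 3 other scalings. A narrower range of Cy5 was argued against as the whole cause by reading both stages in Cy5, where 894 and 111 of 10856 sequences gave a ratio of 8.05, but as these were 1059 and 73 on the first array, a part of the excess stays open to the channel or array. After the median log ratio of each of 20 GC groups was taken off, the counts were 1133 and 89, a ratio of 12.73. Taking off group medians could hardly undo 10-fold differences, and it leaves any GC effect on the spread in place. This test therefore could not decide on GC content, which stays open. A difference between larva and egg stays open as a hypothesis beside a deviation of the RNA samples used, which the absence of replicates leaves untested.

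All 8 insulin signature sequences were lower in pupa than in larva. The 5 members that share at most 45 of 60 bases with any other had a median of -2.17, outside the central 95% of random lists (-1.03 to 1.25). As all 8 lay at -1.41 or lower, any 5 of them would have fallen outside that range, so this could not test cross-hybridisation. The values show only that the drop was not confined to the near-identical probes. Cross-hybridisation stays open. After the GC correction the class median was -2.02, with a range of -0.75 to 0.79 for random lists, so sequences of like GC content did not typically share the drop. As the array was already centred, with a median of 0.022, taking off group medians could hardly undo such drops. It also leaves any GC effect on the spread in place, so GC content stays open. A lower level of several insulin-like transcripts in the pupal RNA is a hypothesis that remains, and the number of transcripts behind the 8 probes is not known here.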

How the results depend on the processing

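Every setting was fixed before the data were examined except those for 10-fold counts, for the stage of highest level, for egg against adult, for sequence classes and for counting repeated probes. The counts at 2-fold stayed within 1.5 times the loess value under all settings run, with 5 exceptions. Sequences higher in egg numbered 3808 by the scanner software's ratio, 3812 by the value table and 4448 without normalization, against 1899. Without normalization 729 were higher in adult (2185) and 6441 in pupa (1927). Of the loess calls, 0 were 2-fold apart the other way under any setting, except 19 for pupa and adult without normalization. Leaving out saturated spots changed nothing because none was saturated. For the stages on 2 arrays, the correlation became 0.9933 without Aquantile and 0.9922 by processed signals for larva (0.9925), and 0.9953 with no dim filter and 0.9932 by processed signals for pupa (0.9940). The SD became 0.360 without Aquantile, 0.395 with no dim filter and 0.404 by processed signals for larva (0.339), and 0.345, 0.293 and 0.367 for pupa (0.306). By the scanner software's ratio, a trough in larva was shown by 718 sequences (427), lower values at the first and second step by 120 (37), under 2-fold throughout by 2677 (4168) and lower at every step by 11 (4). Median centring gave 118 lower at the first and second step (37), 132 higher (204) and 418 lower (236) at the second and the third, 28 higher (59) and 76 lower (4) at every step. With no dim filter 355 were higher at the second and the third step (204) and 6467 under 2-fold throughout (4168). A threshold of 1.5-fold gave 1056 larval troughs (427), 1093 pupal peaks (644), 1095 pupal troughs (586), 147 lower at the first and second step (37), 514 higher (204) and 585 lower (236) at the second and the third, 185 higher (59) and 38 lower (4) at every step, and 1670 under that threshold throughout. At 3-fold these were 120, 396, 250, 10, 91, 95, 23, 1 and 6679, with 812 larval peaks (1243) and 341 higher at the first and second step (573). The cause of these moves was not tested, beyond the thresholds themselves and the filter adding sequences. Of the class medians outside the central 95% of random lists, 1 turned direction: P450 from pupa to adult, at -0.09 without normalization against 0.83. Of those inside it, 6 turned without normalization. From pupa to adult these were insulin at -0.67 (0.18), kinase at -0.33 (1.29) and glycine-rich at -0.62 (0.70). Glycine-rich turned from egg to larva at -0.24 (0.19), and WD repeat at -0.03 (0.33) and basic at -0.06 (0.04) from larva to pupa. None of these medians turned after median centring, which differs from no normalization only by a constant for each array. Class percentiles were the same under both, at 98.89 for P450 from pupa to adult. The turns without normalization were thus shifts of the whole array and not of a class within it. Means in place of medians turned 6 of those inside. They were acidic at 0.30 (-0.16) and basic at 0.35 (-0.02) from egg to larva, kinase at 0.60 (-0.08) and EF-hand at -0.48 (0.34) from larva to pupa, and EF-hand at 0.37 (-0.10) and acidic at 0.06 (-0.09) from pupa to adult. No named probe turned, but 8 of their values moved by more than the scanner software's error, the most for sw13913 at -11.69 by that software's ratio (-9.35). No paired analysis was possible because each comparison has 1 array. Counting genes in place of probes, and the fixed gene lists, were not run because the probes have no gene names. Signal over background, lowest for egg at 13.8, limits ratios of dim probes.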

Other observations

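The counts of sequences by stage of highest level were chosen after the data had been seen. Only the 10856 sequences measured on all 3 arrays entered, so a sequence not well above background in some stage was left out. The egg probes sw13913 and sw09144 were left out in this way, so the counts miss sequences confined to few stages. Levels summed over the steps placed 1003 sequences at least 2-fold above every other stage in adult, 818 in egg, 800 in larva and 489 in pupa. At 10-fold the order was different, with 287 sequences in larva, 104 in adult, 71 in pupa and 19 in egg. The scanner software's ratio gave 1902 in egg, 1021 in adult, 762 in larva and 468 in pupa at 2-fold, and median centring gave 1448, 598, 837 and 496, so the places of egg and adult depended on the scaling. At 10-fold larva led under each of the 3 scalings, with 287, 287 and 273 sequences.

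The 4 homeodomain sequences measured in egg and larva included 2 that were measured on all arrays, which had ratios of -0.08 and -0.90 from larva to pupa and 0.90 and 2.08 from pupa to adult. The insulin signature sequence higher in egg than in larva, reading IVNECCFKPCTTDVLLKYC before a stop, had log2 ratios of -2.36, -2.22 and 1.35 at the 3 steps.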
